A study of Drosophila melanogaster with 64 samples.

How the data were processed

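Heads of male w1118 flies were sequenced after traumatic brain injury (TBI), after a sham procedure, and from uninjured flies, with 20 heads per sample. Per the labels, flies were reared at 25 C with 12 h of light and injured at 3 d of age. The libraries were made from polyA RNA with a stranded kit and sequenced on a NextSeq instrument. The table deposited by the authors holds gene counts from HTSeq, 1 column per library, for 17481 genes and 5 categories of reads that were not assigned. Per the submitters' processing notes, reads were checked with FastQC and MultiQC, aligned with HISAT2, processed with Picard and counted with HTSeq, and DESeq2 was used for their own tests. The versions of these tools, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The values were whole numbers, and the counts were used as deposited. Of the gene identifiers 17343 were matched to a symbol in the BDGP6.54 annotation (Ensembl release 115) and 138 were not; positions are those of that annotation.

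The 64 libraries were grouped by condition, time and library day, as labelled. Library day 1 held 31 libraries with 9.16 to 26.4 M gene counts (median 16.1 M), and library day 2 held 33 libraries with 18.6 to 44.9 M (median 24.3 M). The genes took 78.2% to 86.0% of all reads on day 1 and 67.9% to 79.0% on day 2. Reads not aligned made up 3.54% to 10.8% on day 1 and 9.78% to 11.9% on day 2, and reads aligned at more than 1 place 3.57% to 4.92% and 4.04% to 16.5%. The labels give 55 separate RNAs, 9 of which (the controls and the 24 h groups) were prepared on both days. The series text gives 52 unique RNA samples, a difference that the sources used here leave open. As the same RNA gave different levels on each day, the days were kept apart and by the labels no RNA was counted more than once in a test.

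Tests were made in R 4.3.3 with edgeR 4.0.16. For each library day 1 quasi-likelihood model with 11 groups was fitted, with TMM factors, genes kept by filterByExpr and robust estimation of the spread. This kept 10739 genes on day 2 and 10567 on day 1, with 22 and 20 residual degrees of freedom and a biological coefficient of variation of 0.167 and 0.161. TBI was compared with sham at each time and sham with the control at each time, and a joint test asked whether the TBI effect differed between the 5 times of a library day. The library days were compared on the 9 RNAs prepared on both, with the RNA as a block. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Standard errors were the absolute log2 fold change divided by the square root of the F statistic. Levels (CPM) are counts scaled by library size and TMM factor, and log values in figures add 1. Sums over gene lists were scaled by library size alone, as were the levels of tim, Clk, AttC, Cyp4g1 and the yolk protein genes in single libraries.

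Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data; p-values were adjusted over the lists of each comparison. The 25 lists fixed in advance covered antimicrobial peptides, the Toll and Imd pathways, AP-1 and JNK, JAK/STAT, heat shock, detoxification, endoplasmic reticulum stress, activity-regulated genes, glycolysis, oxidative phosphorylation, synapses, photoreceptors, glia, fat body, hemocytes, muscle, gut, male reproductive genes, the clock, the proteasome, ribosomal proteins, autophagy, DNA damage, starvation and FoxO, and cuticle repair. Another 6 lists were added after the data were seen: the mitochondrial genome, oenocytes and fatty acids, the Arp2/3 complex, ESCRT-III, integrin adhesion and the Tsp42E cluster. Lists with fewer than 3 measured genes were not tested. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the genes of 1 list. Of the list tests of all comparisons 202 passed with the preset correlation and 27 with an estimated one.

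The groups, comparisons, tests, lists and the rule for naming genes were chosen before the data were examined. The rule named up to 8 higher and 8 lower genes per comparison with the largest log2 fold change among those that passed, had a mean of at least 2 CPM and no overlap between replicates; up to 4 passing members of each list; and 18 genes followed at every time after TBI. These were kay, Jra, Mmp1, Ets21C, puc, upd3, AttC, DptA, Drs, Mtk, TotA, Hsp22, Hsp70Bc, GstD1, Hr38, elav, repo and ninaE. The text names fewer where a gene had been named at another time.

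The alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0 in place of edgeR, the replicate number as a block, a model of only the 2 groups compared, the sum of both libraries of each RNA at 24 h, and leaving out each library in turn. For the gene lists these were the estimated correlation and the fry test. After the data were seen, 2 more were added: scaling without the genes of the mitochondrial genome, and sham at 12 h with replicate 2 alone. Whether replicate numbers pair sham with TBI was checked by the correlation of each sample's deviations from its group; pairing was taken to hold where there were 3 pairs and every pair had r over 0.1, which was so at 1 h, 6 h, 24 h of day 2, 3 d and 10 d. The chi-squared per degree of freedom between replicates was 11.0 to 249 over 62 pairs, far above 1, so no library was a copy of another of its group. Between the libraries of the same RNA on both days it was 97.9 to 313 over 9 pairs. No other libraries of different groups were compared in this way.

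Precision was tested on simulated data in which genes were changed by a known fold. Counts were drawn from the fitted mean and spread of each gene, independently between genes and without pairing or outlying libraries. The rates below hold for such data and may be too favourable for the real libraries. At 24 h of day 2 the test recovered 44.6% of changes of 1.5-fold, 80.3% of 2-fold and 93.9% of 4-fold, with 14 false calls of 158. At 15 d, with 2 samples per group, it recovered 15.2%, 67.2% and 83.3%, with 3 false calls of 113. No library was left out of the tests. The 5 categories of unassigned reads were used only to describe depth and single libraries, and the raw reads were not used here.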

Results

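Transcript levels were measured by RNA sequencing in heads of male w1118 flies after traumatic brain injury (TBI), after a sham procedure, and in uninjured controls at time 0. Flies were injured at 3 d of age, and 20 heads made up each sample. The sham and TBI samples were collected at 1, 3, 6, 12 and 24 h and at 3, 7, 10 and 15 d, with 3 samples per group and 2 at 15 d. Replicates were separate samples of heads, so the standard errors and p-values measure the spread between such samples. Libraries were prepared on 2 days. Day 1 held the controls, 24 h and all later times (31 libraries), and day 2 held the controls and all times up to 24 h (33 libraries). The controls and both 24 h groups were thus sequenced on each day. The gene counts per library ran from 9.16 to 26.4 M on day 1 (median 16.1) and from 18.6 to 44.9 M on day 2 (median 24.3). After the filter on low counts, 10739 genes were tested on day 2 and 10567 on day 1. Below, a gene rose or fell where the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05. Values are log2 fold changes ± standard error, with levels as counts scaled by library size and TMM factor (CPM ± SD, n = 3 per group unless stated).

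The comparison of TBI with sham at each time asked which transcripts the injury itself moved, beyond handling and age. On day 2 it gave 794 genes at 1 h, 1775 at 3 h, 1304 at 6 h, 926 at 12 h and 902 at 24 h. On day 1 it gave 1587 genes at 24 h, 143 at 3 d, 24 at 7 d, 50 at 10 d and 4 at 15 d. Of the genes that rose at any time of day 2, 165 rose at all 5 times, where independent lists of these sizes would share 0.0137. Of those that fell, 23 fell at all 5 times (0.000529 by the same reckoning). Among the 165 were genes of the actin cytoskeleton, such as Act5C and Act42A, and the annexins AnxB9 and AnxB11. AkhR, the receptor of the adipokinetic hormone, was among the 23.

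**Figure D1:**
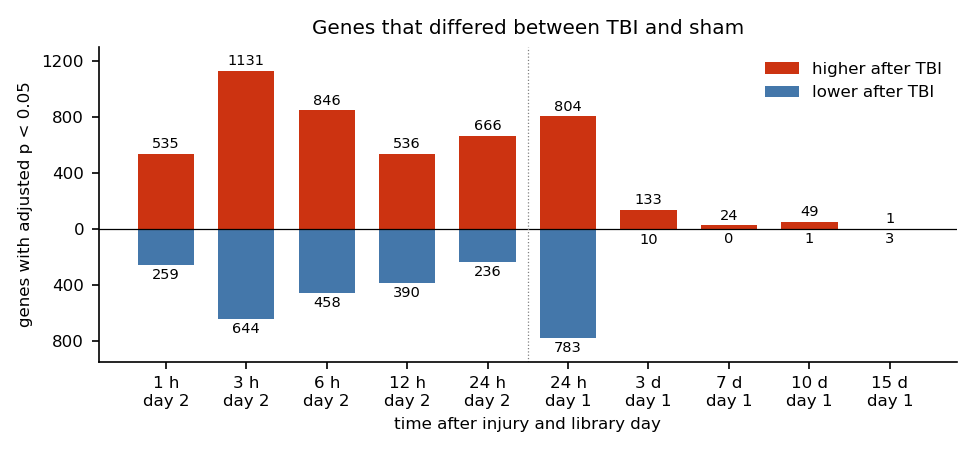
Number of genes with an adjusted p under 0.05 in TBI against sham (vertical axis, genes; higher after TBI above 0, lower below) at each time after injury and library day (horizontal axis). At 3 h 1131 genes were higher and 644 lower, at 24 h of day 1 804 and 783, and at 15 d 1 and 3.

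At 1 h after TBI, genes of the AP-1 and JNK response rose, and so did the cytokine gene upd2 (3.80 ± 0.37). Ets21C, an ETS transcription factor acting downstream of JNK, rose from 7.06 ± 1.31 CPM in sham to 91.1 ± 16.6 CPM (3.69 ± 0.24, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.74e-11). Ets21C (FBgn0005660) lies on chromosome 2L, 544925 to 552923, minus strand. Mmp1 (FBgn0035049), a matrix metalloproteinase, lies on chromosome 2R, 24671294 to 24688184, minus strand, and upd3 (FBgn0053542) on chromosome X, 18277233 to 18284596, plus strand (build BDGP6.54, annotation release 115). Immediate-early genes rose with them, among them hry (2.62 ± 0.35), a transcriptional repressor, and kay (1.40 ± 0.15), the Fos subunit of AP-1. Also higher were ninaD (2.81 ± 0.34), a scavenger receptor for carotenoids, and the integrin subunit ItgaPS4 (2.66 ± 0.29). The glial transcription factor repo fell (-1.08 ± 0.14), as did Mdr65 (-1.50 ± 0.36), a transporter of the blood-brain barrier, Cyp18a1 (-1.85 ± 0.28), which inactivates the moulting hormone, and the peptidase gene Nepl9 (-2.15 ± 0.30). In the AP-1 and JNK list 10 of 19 genes rose (11 adjusted over the list alone), with an adjusted p of 1.68e-04 in limma's camera with an estimated correlation. In the activity-regulated list 7 of 13 rose (10 adjusted over the list alone; 7.63e-04 in the same test). In the JAK/STAT list 4 rose and 1 fell of 16 (4 and 2 adjusted over the list alone), and the list did not pass with an estimated correlation (limma's camera, adjusted p = 0.179). Toll pathway members dl (1.53 ± 0.11), an NF-kB factor, and spz (1.20 ± 0.21), its ligand, rose. The Toll and Imd list did not pass as a whole (4 of 33 higher, 4 adjusted over the list alone, adjusted p in limma's camera = 0.0576). Of all 794 genes, 535 rose and 259 fell. The count was 498 without TBI replicate 1, 526 without sham replicate 1 and 517 without sham replicate 3.

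At 3 h the cytokine genes rose, upd3 by 5.51 ± 0.43 and upd2 by 5.09 ± 0.39. Ets21C (4.67 ± 0.25, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.89e-12), ninaD (4.33 ± 0.37), the replication licensing factor Cdc6 (4.69 ± 0.54) and mesh (3.81 ± 0.39), a septate junction protein, rose. Lower genes included ana (-2.82 ± 0.26), a glycoprotein secreted by glia, Mdr65 (-2.21 ± 0.37), the predicted transporter gene CG8654 (-2.87 ± 0.26) and repo (-1.09 ± 0.14). Heat-shock genes rose in number, Hsp70Aa by 2.71 ± 0.72, Hsp27 by 2.20 ± 0.63 and the small heat-shock gene l(2)efl by 1.97 ± 0.29. Of their list 10 of 20 rose (13 adjusted over the list alone). The list as a whole did not pass with an estimated correlation (limma's camera, adjusted p = 0.281, against 2.11e-04 with the preset one). The copies of Hsp70 are nearly identical, so how their reads were divided is uncertain. In the JAK/STAT list 7 of 16 genes rose (8 adjusted over the list alone, adjusted p = 0.0226 in limma's camera with an estimated correlation). In the AP-1 and JNK list 12 rose and 2 fell of 19 (13 and 2 adjusted over the list alone, and 0.00393 in that test). Members of the Toll and Imd list rose, among them the recognition protein PGRP-SA (1.78 ± 0.43) and the NF-kB factor Rel (1.42 ± 0.27). They numbered 10 of 33 (13 higher and 1 lower adjusted over the list alone), and limma's camera with an estimated correlation gave adjusted p = 0.654. The fat body genes apolpp (-1.36 ± 0.25), a lipoprotein, and FASN1 (-0.82 ± 0.22), a fatty acid synthase, fell. The antisense transcripts asRNA:CR44205 (4.45 ± 0.49) and asRNA:CR44207 (4.12 ± 0.72) also rose. The strand setting of the counting is not given in the sources used here, so their reads and those of the opposite strand cannot be told apart. In all 1131 genes rose and 644 fell. Of these, 609 of those higher and 250 of those lower were shared with 6 h, against 89.1 and 27.5 for independent lists. Without TBI replicate 3 the split at 3 h was 1055 higher and 376 lower, and without sham replicate 1 820 and 423.

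At 6 h the cytokine and AP-1 response held and the Turandot genes, secreted stress proteins, joined it. CG13992, which has no known function, rose from 0.00764 ± 0.0132 to 5.28 ± 0.937 CPM. Sfp53D (5.89 ± 0.53), a seminal fluid protein gene, rose. The cytokine gene upd3 was higher by 5.45 ± 0.45 and Ets21C by 4.61 ± 0.27. TotM (4.36 ± 0.65) and TotB (4.45 ± 0.61) rose, as did TotA on chromosome 3R, 20871036 to 20871700, plus strand (FBgn0028396, 2.64 ± 0.39, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.78e-05). The antimicrobial peptide genes Listericin (2.39 ± 0.46), AttD (2.79 ± 0.80) and Def (2.12 ± 0.64) rose. Enzymes of glycolysis fell, among them Pgk (-0.56 ± 0.15), Tpi (-0.50 ± 0.11) and Pfk (-0.45 ± 0.09). Of their list 7 of 13 were lower (10 lower and 1 higher adjusted over the list alone, camera in limma adjusted p = 0.0443 with an estimated correlation). Nepl5 (-2.11 ± 0.40), a peptidase, Hpd (-1.91 ± 0.42), which breaks down tyrosine, and Pcyt2 (-1.90 ± 0.22), an enzyme of phospholipid synthesis, also fell. In the JAK/STAT list 9 of 16 rose (10 adjusted over the list alone; adjusted p = 0.00130 in limma's camera with an estimated correlation). In the AP-1 and JNK list 11 rose and 2 fell, over all genes and adjusted over the list alone (0.00174). Heat-shock genes were higher (8 of 20, 10 adjusted over the list alone) and fat body genes lower (4 of 16, 8 lower and 1 higher adjusted over the list alone). For these lists the adjusted p of limma's camera was 0.291 and 0.339 with an estimated correlation. Of the 1304 genes, 846 rose and 458 fell. Without TBI replicate 1 the split was 559 higher and 514 lower, and without TBI replicate 3 857 and 273.

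At 12 h the Turandot genes and Diedel, a circulating immune regulator, rose, TotM by 6.54 ± 0.73, Diedel by 6.01 ± 0.64 and TotC by 5.0 ± 0.6. nerfin-1 (FBgn0028999; chromosome 3L, 909112 to 912319, plus strand), a zinc-finger factor of neuronal differentiation, rose to 13.1 ± 2.04 CPM from 0.628 ± 0.222 CPM in sham (4.40 ± 0.27, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.40e-11). The storage protein genes of the fat body fell, Lsp2 by 2.80 ± 0.64 and Lsp1beta by 2.51 ± 0.56 on the log2 scale, as did the alkaline phosphatase gene phu (-2.21 ± 0.54). The library labelled sham 12h replicate 3 had a mean score of 54 age-dependent nuclear genes like that of older flies, although single genes went the other way. Its share of mitochondrial transcripts (11.2%) was above that of all libraries at 7 d or later. Without that library 804 genes passed (518 higher, 286 lower), of which 651 were among the 926 (536 higher, 390 lower). Ets21C, upd3, TotM, nerfin-1 and Lsp2 passed either way, while the lower values of Clk, cry, Yp1 and ninaE, the main rhodopsin gene, passed only with that library. In the JAK/STAT list 9 of 16 rose, over all genes and adjusted over the list alone (adjusted p = 2.72e-04 in limma's camera with an estimated correlation). In the AP-1 and JNK list 8 of 19 did (9 adjusted over the list alone; 0.00103). Glycolysis genes were again lower (5 of 13, 11 adjusted over the list alone; 0.0134), with Pgi at -0.82 ± 0.15. Without the library labelled sham 12h replicate 3 Pgi was -0.48, and Gapdh1, 1 of the 5, did not pass (edgeR adjusted p = 0.0919, against 0.0153 with it).

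At 24 h the Turandot genes, nerfin-1 and the C-type lectin gene CG7763 rose on both library days. On day 2 TotM rose by 5.39 ± 0.69, TotC by 5.29 ± 0.59, CG7763 by 5.20 ± 0.66 and nerfin-1 by 5.05 ± 0.26. On day 1 the values were 5.37 ± 0.86, 5.49 ± 0.94, 5.06 ± 0.67 and 5.19 ± 0.33. The edgeR quasi-likelihood test gave nerfin-1 a Benjamini-Hochberg adjusted p of 2.85e-13 on day 2 and 1.20e-10 on day 1. Lsp2 (FBgn0002565) lies on chromosome 3L, 12129393 to 12131869, plus strand. On days 2 and 1 it fell by 3.20 ± 0.66 and 3.19 ± 0.71 on the log2 scale, Lsp1beta by 2.72 ± 0.58 and 2.71 ± 0.63, and tobi, an intestinal glucosidase controlled by insulin, by 1.97 ± 0.50 and 1.99 ± 0.51. The antimicrobial peptide gene Def rose by 2.91 ± 0.67 and 3.56 ± 0.76. JAK/STAT genes rose on both days, 9 of 16 each (10 on day 2, and 10 higher with 2 lower on day 1, adjusted over the list alone). The adjusted p of limma's camera with an estimated correlation was 9.05e-04 on day 2 and 0.0217 on day 1. AP-1 and JNK genes rose too, 11 of 19 on day 2 and 9 with 1 lower on day 1 (11 on day 2, and 10 with 2 lower on day 1, adjusted over the list alone). In the same test of limma their adjusted p was 0.00572 and 0.0392.

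The 24 h counts were 902 on day 2 (666 higher, 236 lower) and 1587 on day 1 (804 higher, 783 lower). On day 2 the count was 576 without sham replicate 1, 562 without TBI replicate 1 and 565 without TBI replicate 3, and 1372 with the replicate number as a block. On day 1 it was 601 without sham replicate 1 (404 higher, 197 lower), a library with 10.5% of reads not aligned against 4.24% and 4.69% in replicates 2 and 3. It was 1016 without sham replicate 2 (548 and 468), 775 without TBI replicate 1 (507 and 268) and 656 without TBI replicate 3 (433 and 223). Single synaptic genes passed in edgeR on day 1 and not on day 2, where the median of the 20 was -0.28 (-0.40 on day 1). On day 1 14 of 20 fell (18 adjusted over the list alone), among them the GABA-synthesising enzyme Gad1 (-0.64 ± 0.12), the calcium sensor Syt1 (-0.63 ± 0.14) and the acetylcholine transporter VAChT (-0.61 ± 0.14). Without sham replicate 1 of day 1 Gad1 still passed, and Syt1 and VAChT did not. The list did not pass with an estimated correlation (limma's camera, adjusted p = 0.530). Proteasome genes (12 of 31 higher, 20 adjusted over the list alone) and ribosomal protein genes (15 of 82, 21 adjusted over the list alone) rose on day 1. Each list had an adjusted p of 0.578 in limma's camera with an estimated correlation. Whether these lists differed between the library days was not tested.

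Since the 9 RNAs of the controls and the 24 h groups were prepared on both days, the 24 h response could be set side by side. Across the 10357 genes tested on both days the log2 fold changes had a Pearson r of 0.848, and 82.1% had the same sign. Genes are not independent replicates, and the same RNA was used on both days, so this measures the library preparation and not the animals. Among 1833 genes that passed on either day, 99.5% had the same sign, 486 rose on both days and 145 fell on both, against 50.1 and 17.7 for independent lists, and 0 passed in opposite directions (edgeR on each day). Without sham 24h replicate 3 the r of all genes was 0.796. It was 0.342 with no filter on low counts and 0.40 with DESeq2, where genes of low counts are compared too.

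**Figure D2:**
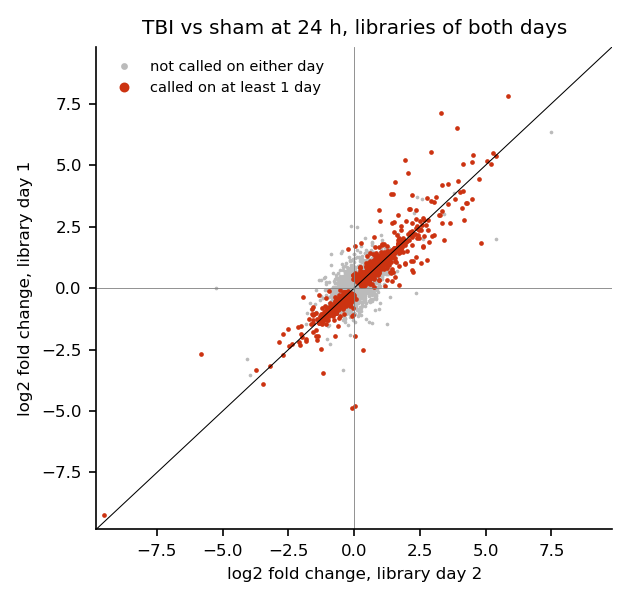
Log2 fold change of TBI against sham at 24 h in the libraries of day 2 (horizontal axis) and day 1 (vertical axis), 1 point per gene, red where the gene passed on at least 1 day and grey elsewhere, with the line of equal values. The red points, 1833 genes, lie along the line, with r = 0.927 among them.

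At 3 d nerfin-1 was still higher (5.67 ± 0.34, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.83e-11), at 28.1 ± 7.64 CPM against 0.543 ± 0.0720 CPM in sham. CG7763 (4.66 ± 0.66), Def (3.53 ± 0.78), the leucine-rich repeat gene atk (3.44 ± 0.63) and the phagocytic receptor NimC4 (3.80 ± 0.61) rose, and AkhR (-1.01 ± 0.17) and Ork1 (-0.66 ± 0.15), a potassium channel, fell. Ets21C (2.13 ± 0.50), Mmp1 (1.22 ± 0.21), puc (0.77 ± 0.11), the phosphatase that limits JNK, and upd3 (2.91 ± 0.61) were still higher. Of their list 4 of 19 genes rose (8 adjusted over the list alone, limma's camera adjusted p = 0.0316 with an estimated correlation). Muscle genes such as Act87E (1.59 ± 0.34) rose (3 of 16; 10 adjusted over the list alone), and so did heat-shock genes (3 of 19; 10 adjusted over the list alone). For these lists limma's camera with an estimated correlation gave adjusted p = 0.0803 and 0.0803. Of the 143 genes, 133 rose and 10 fell, and 102 of those higher had also risen at 24 h on day 1, against 10.1 for independent lists. The count was 53, 48 and 60 without sham replicate 1, 2 and 3 in turn and 36 without TBI replicate 2, and 252 with the replicate number as a block.

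At 7 d immune genes were among those that rose. The Bomanin gene BomS1 (FBgn0034329, on chromosome 2R, 18383949 to 18384378, plus strand), a target of the Toll pathway, rose from 47.6 ± 1.20 to 239 ± 42.9 CPM (2.33 ± 0.46, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0308). With it rose Listericin (2.25 ± 0.45), Bbd (2.03 ± 0.41), needed for Bomanin activity, the recognition protein PGRP-SD (1.61 ± 0.27) and the serine protease l(2)k05911 (3.54 ± 0.60). The last (FBgn0284244) lies on chromosome 2L, 13251509 to 13257426, plus strand. Of the antimicrobial peptide genes 7 of 32 rose, and 31 did so adjusted over the list alone (limma's camera, adjusted p = 7.25e-04 with an estimated correlation). The list member AttC was low in sham at 7 d (67.7, 30.5 and 115 CPM), against 606, 416 and 741 CPM in sham at 24 h of day 1. After TBI at 7 d it was 613, 523 and 337 CPM, and in the controls of day 1 22.9, 300 and 92.4 CPM. BomS1 differed less, with 59.6, 96.4 and 50.3 CPM in sham at 24 h of day 1. How far a low sham level made the difference of the list was not tested. Of the Toll and Imd list 2 of 33 rose and 13 adjusted over the list alone (0.00590). In all 24 genes rose and 0 fell (681 at an unadjusted p under 0.05 in edgeR; DESeq2 called 113, all higher). The count rested on single libraries: it was 0, 4 and 0 without sham replicate 1, 2 and 3 in turn, and 5, 7 and 40 without TBI replicate 1, 2 and 3. In TBI replicate 1 Cyp4g1 stood at 587 CPM, against 0.469 CPM or less in the sham libraries at 7 d.

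At 10 d l(2)k05911 (4.07 ± 0.57) and CG7763 (3.13 ± 0.56) were higher again, with the odorant-binding protein gene Obp83a (5.96 ± 1.24), the lipase gene mag (4.37 ± 0.94) and the acyl-CoA synthetase gene Acsx2 (2.91 ± 0.66). The sum of the gut genes was higher in each TBI library than in the sham library of its number (358, 332 and 817 CPM against 128, 189.8 and 424 CPM), while the gut list did not pass (limma's camera, adjusted p = 0.729). BomS5 (1.55 ± 0.23), PGRP-SA (1.73 ± 0.39) and Rel (0.87 ± 0.19) rose, and Dsk, a neuropeptide of satiety, fell (-0.92 ± 0.17, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0102). The antimicrobial peptide list (1 of 32 higher, 14 adjusted over the list alone) and the Toll and Imd list (2 of 33, 7 adjusted over the list alone) both had an adjusted p in limma's camera of 0.0389 with an estimated correlation. Of the 50 genes 49 rose. Without TBI replicate 3 the calls of Obp83a, mag, Acsx2, PGRP-SA, Rel and Dsk did not pass, while those of l(2)k05911, CG7763 and BomS5 did. The 7 d and 10 d lists shared 9 genes, against 0.111 for independent lists. CG12814, CG15546, CG4269 and Skel rose at 24 h, 3 d, 7 d and 10 d of day 1. The count was 14, 2 and 6 without sham replicate 1, 2 and 3 in turn, 81, 19 and 12 without TBI replicate 1, 2 and 3, and 113 with the replicate number as a block. At 15 d, with 2 samples per group, l(2)k05911 rose (4.19 ± 0.68, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0147) and the odorant-binding protein gene Obp56g (-1.82 ± 0.30) and the uncharacterised CG11368 (-1.27 ± 0.23) fell. CG4377 (-1.93 ± 0.34), chosen after its values were seen as its level lay outside the naming rule, also fell. The antimicrobial peptide list had 0 of 32 genes higher over all genes tested and 18 adjusted over the list alone (limma's camera, adjusted p = 0.0591 with an estimated correlation). In edgeR 691 genes had an unadjusted p under 0.05, and DESeq2 called 31 (21 higher, 10 lower). The count of 4 became 1 and 0 without sham replicate 1 and 2 and 42 and 0 without TBI replicate 1 and 2, where the remaining sample was assumed to vary like the other groups.

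**Figure D3:**
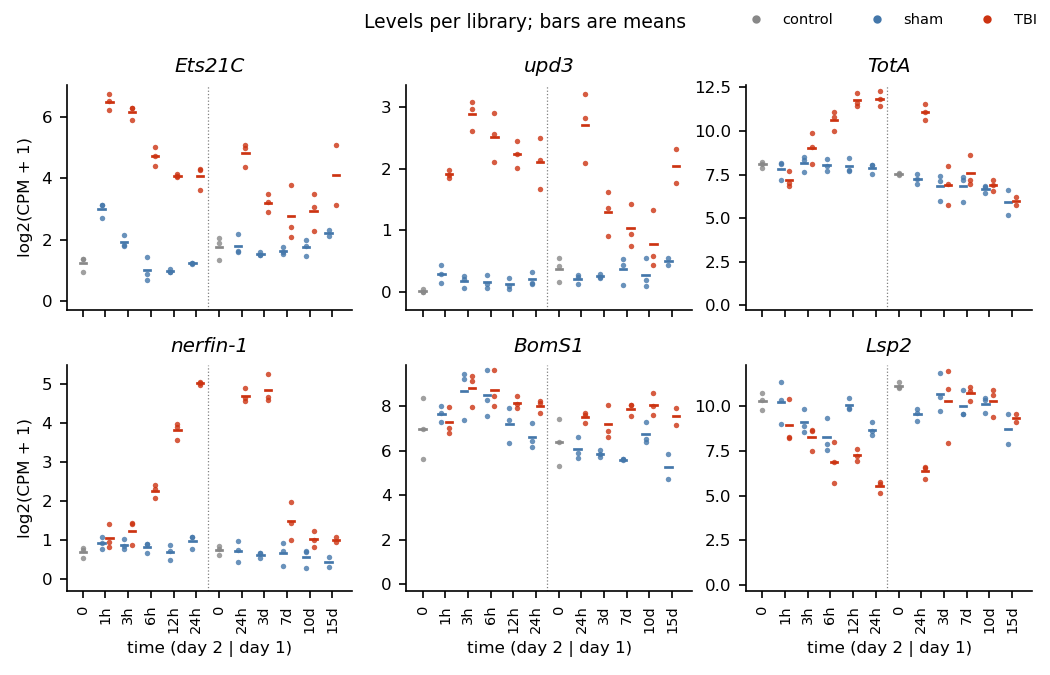
Levels of 6 genes in each library as log2(CPM + 1) (vertical axes) by time (horizontal axes; libraries of day 2 left of the dotted line, day 1 right), with control libraries in grey, sham in blue, TBI in red and bars at the means. Among the times of day 2 the mean of Ets21C after TBI was highest at 1 h (91.1 ± 16.6 CPM) and that of upd3 at 3 h (6.49 ± 1.23 CPM).

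Of the genes followed at every time, Mmp1 and upd3 rose from 1 h to 3 d, Mmp1 by 2.28 ± 0.22 at 1 h, 2.88 ± 0.23 at 3 h and 2.57 ± 0.21 at 24 h of day 1. puc rose at the same times, from 1.60 ± 0.14 at 1 h to 0.76 ± 0.11 at 24 h of day 1, and kay until 24 h, where it was 0.52 ± 0.15 on day 2. After 3 d upd3 did not pass, which does not show that its rise had ended. At 15 d it stood at 2.43 and 4.01 CPM after TBI against 0.354 and 0.474 CPM in sham. At 7 d it was 1.69, 0.672 and 0.928 CPM against 0.359, 0.0864 and 0.446 CPM, while at 10 d the groups overlapped. Jra, the Jun subunit of AP-1, rose at 1 h (1.22 ± 0.17), 3 h (1.36 ± 0.17), 6 h and 24 h on both days. It did not pass at 12 h (0.41 ± 0.17, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.151), but did so without the library labelled sham 12h replicate 3 (0.61, edgeR adjusted p = 0.0256). TotA was not different at 1 h (-0.62 ± 0.37, adjusted p = 0.428 in the same edgeR test) and was 4.01 ± 0.41 and 3.89 ± 0.57 at 24 h on days 2 and 1. Hsp70Bc rose at 1 h (1.82 ± 0.44), 3 h and 6 h, and the glutathione transferase GstD1 at 3 h (0.93 ± 0.22), 6 h and 24 h on both days. At 12 h GstD1 passed only without the library labelled sham 12h replicate 3 (0.92, edgeR adjusted p = 0.00942). The antimicrobial peptide genes AttC, DptA, Drs and Mtk, the activity-regulated nuclear receptor Hr38 and the neuronal marker elav passed at none of the 10 comparisons. At 7 d Drs stood at 4.74 ± 1.67 and Mtk at 2.28 ± 0.73, with a wide spread between samples. repo was lower at 1 h, 3 h and 6 h (-0.56 ± 0.14), and ninaE at 12 h only, a call that rested on the library labelled sham 12h replicate 3. Hsp22 had 0 counts in every library and was not tested.

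**Figure D4:**
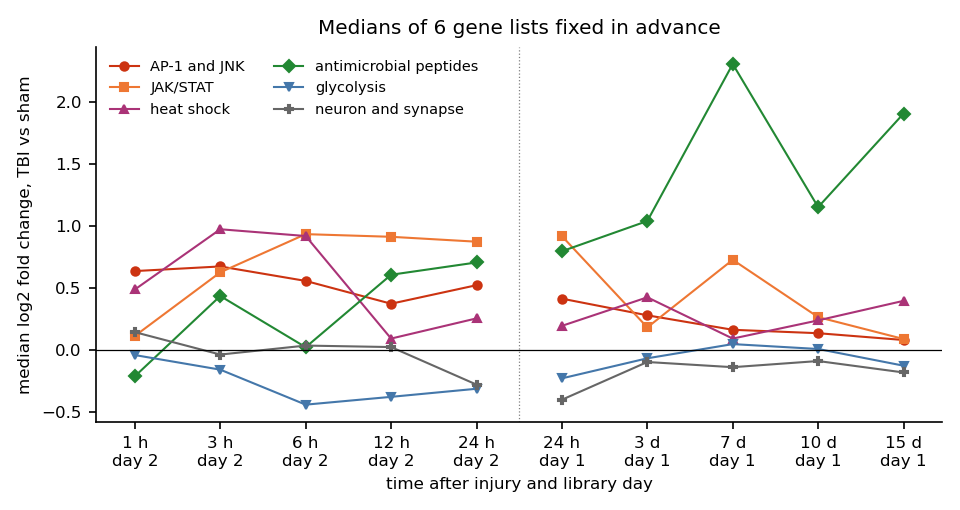
Median log2 fold change of TBI against sham (vertical axis) over 6 gene lists fixed in advance, at each time and library day (horizontal axis). The AP-1 and JNK median was 0.63 at 1 h and 0.08 at 15 d, and that of the antimicrobial peptides was -0.21 at 1 h and 2.30 at 7 d.

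For lists of other functions after TBI, the adjusted p are from limma's camera. Among detoxification genes 4 rose and 5 fell of 32 at 3 h (7 and 6 adjusted over the list alone, limma adjusted p = 0.872), with GstD2 at 2.28 ± 0.52 and Cyp6a8 at -1.62 ± 0.36. Endoplasmic reticulum stress genes had 2 rises of 15 at 1 h (2 adjusted over the list alone, 0.924), 1 of them the kinase PEK (0.50 ± 0.08). Oxidative phosphorylation genes had 6 of 40 lower at 24 h of day 1 (6 adjusted over the list alone), and limma's camera with an estimated correlation gave adjusted p = 0.752. The photoreceptor list (24 genes) had 1 rise, ninaD, and 2 falls at 3 h (1 and 1 adjusted over the list alone, limma adjusted p = 0.434). The glia list had 4 rises, among them Gli (1.00 ± 0.27), and 2 falls of 16 at 1 h (4 and 2 adjusted over the list alone, limma adjusted p = 0.797). It had 4 and 5 at 3 h (4 and 5, limma adjusted p = 0.0751). At 6 h it had 2 rises and 6 falls (2 and 8 adjusted over the list alone, limma adjusted p = 0.546 with an estimated correlation). Hemocyte genes had 1 rise and 2 falls of 15 at 1 h (2 and 4 adjusted over the list alone, limma adjusted p = 0.0785), Hml (-1.83 ± 0.57), a clotting protein, being the largest fall. Of the gut list 2 of 8 rose at 24 h of day 1 (2 adjusted over the list alone, limma adjusted p = 0.263). They were the near-identical amylase genes Amy-p (2.57 ± 0.68) and Amy-d (1.97 ± 0.55), and how the reads were divided between them is uncertain. The sum of the gut genes after TBI was 225, 192 and 215 CPM on that day, against 33.6, 49.4 and 56.3 CPM in sham. At 24 h of day 2 it was 33.5, 30.8 and 39.4 CPM against 9.80, 10.7 and 16.8 CPM, and at 7 d 367, 108 and 372 CPM against 50.2, 106 and 178 CPM. The male reproductive list had 1 measured gene on day 2, Acp53Ea, which rose at 1 h, 3 h and 6 h (2.42 ± 0.43), too few for a test of the list. Clock genes had 2 rises and 1 fall of 10 at 24 h of day 1 (2 and 2 adjusted over the list alone, limma adjusted p = 0.728). Autophagy genes had 2 falls of 20 at 3 h (2 adjusted over the list alone, limma adjusted p = 0.0817). DNA damage genes had 4 rises and 1 fall of 20 (5 and 2 adjusted over the list alone, limma adjusted p = 0.434), among them p53 (0.55 ± 0.11). In the starvation and FoxO list 1 rose and 4 fell of 11 at 3 h (3 and 5 adjusted over the list alone, limma adjusted p = 0.0817). In the cuticle repair list 5 of 14 rose (5 adjusted over the list alone, limma adjusted p = 0.481 with an estimated correlation), led by the serpin gene Spn28Dc (2.59 ± 0.39).

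Lists of the cytoskeleton and of membrane repair were added after the data were seen, so their p is not adjusted. Such a p describes the list and is no independent test of it. All 8 genes of the Arp2/3 complex, which branches actin filaments, rose at 3 h and at 24 h on both days (8 adjusted over the list alone each time), with an unadjusted p of 3.64e-05 at 24 h of day 2 in limma's camera with an estimated correlation. Of the ESCRT-III list, which seals membranes, 9 of 9 rose at 3 h and 9 of 9 at 24 h of day 1 (9 adjusted over the list alone each time). Of the integrin adhesion list 9 of 14 rose at 3 h (10 adjusted over the list alone), and of the tetraspanin genes in the 42E cluster 10 of 16 (10 adjusted over the list alone). The oenocyte and fatty acid list, also added, had 6 of 6 higher in sham at 15 d than in controls (6 adjusted over the list alone), and did not pass with an estimated correlation (limma's camera, unadjusted p = 0.315).

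A test of whether the TBI effect differed between the 5 times of a library day gave 395 genes on day 2 and 43 on day 1. With the replicate number as a block it gave 821 and 119, and in DESeq2 688 and 160. On day 2 the effect of TotA, which was -0.62 at 1 h and 4.01 at 24 h, differed between times (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.38e-06). So did that of repo (1.69e-04), -1.08 at 1 h and 0.09 at 24 h. On day 1 the effect on Mmp1 differed (0.00281 by the same test), from 2.57 at 24 h to 0.62 at 10 d. The count on day 1 was 88 without TBI 24h replicate 2. It was 21, 20 and 27 without sham 24h replicate 1, 2 and 3 in turn, and 19 and 25 without TBI 24h replicate 1 and 3. Among the later libraries it was 25 without sham 3d replicate 2, 23 without sham 7d replicate 3. It was 24 and 21 without sham 10d replicate 1 and 2, and 24 without TBI 10d replicate 2 and 27 without either sham 15d library.

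The comparison of sham with the uninjured controls asked what handling, time of day and age moved without the injury. All sham groups of a library day share the same 3 control libraries. At 1 h after the sham procedure, Ets21C rose by 2.35 ± 0.26. Gadd45, a stress-induced regulator of the kinase cascade upstream of JNK, rose by 2.17 ± 0.20 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.49e-07). The NF-kB factor Rel rose by 1.68 ± 0.27 and Hr38 (FBgn0014859, on chromosome 2L, 20683462 to 20714588, minus strand) by 1.81 ± 0.39. The heat-shock genes Hsp68 (-1.61 ± 0.36) and DnaJ-1 (-1.06 ± 0.14) and the nutrient-responsive factor sug (-2.30 ± 0.39) fell. The AP-1 and JNK list (4 of 19 higher, 6 adjusted over the list alone) had adjusted p = 7.38e-04 in limma's camera with an estimated correlation. The activity-regulated list (3 of 13 higher, 4 higher and 1 lower adjusted over the list alone) and the heat-shock list (2 of 20 lower, 4 adjusted over the list alone) both gave 0.0195. Of 47 genes 42 rose. The count was 26 and 25 without control replicate 2 and 3 and 17 without sham replicate 2.

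At 3 h after the sham procedure Hsp68 (-1.98 ± 0.36), Hsp83 (-1.27 ± 0.23), the Hsp90 gene, and Hr38 (-2.22 ± 0.40) were lower, and spz3 (1.72 ± 0.24) and the oxidase gene Duox (1.07 ± 0.16) were higher. The heat-shock list was lower (3 of 20, 13 adjusted over the list alone; camera adjusted p = 0.0253 with an estimated correlation). Of 39 genes 25 rose and 14 fell, and the count rested on single libraries. It was 1527 without control replicate 1, 12 without control replicate 3, 10 without sham replicate 1 and 65 without sham replicate 3.

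At 6 h and 12 h the clock genes separated sham from control. At 6 h tim (FBgn0014396, on chromosome 2L, 3493986 to 3508119, minus strand) rose by 3.28 ± 0.52, vri by 3.17 ± 0.52 and per by 2.48 ± 0.40. At 12 h tim was higher by 3.51 ± 0.53, vri by 3.33 ± 0.52 and per by 2.38 ± 0.40. Without the library labelled sham 12h replicate 3 the 12 h values were 4.05 for tim, 3.85 for vri and 2.87 for per. The spread of each gene was estimated over all groups of day 2, that library included. It therefore also enters the standard errors and calls at 1 h, 3 h, 6 h and 24 h of day 2. For the single comparisons at those times only the model of the 2 groups compared leaves it out. Achl (-5.41 ± 0.43), an RNA-binding protein gene, and Hr38 (-2.96 ± 0.41, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.37e-04) fell at 6 h. Hr38 (-3.63 ± 0.42), sr (-2.37 ± 0.33), an early growth response factor, and Jhbp5 (-2.19 ± 0.19), which binds juvenile hormone, were lower at 12 h. The hour of day of each collection is not given in the sources used here. The clock list had 3 rises and 1 fall of 10 at 6 h and 4 rises at 12 h (4 and 2 at each time adjusted over the list alone), with adjusted p in limma's camera = 0.111 and 0.353 with an estimated correlation. With the preset one the 12 h list had an adjusted p of 0.191 in limma's camera, and 0.00813 without the library labelled sham 12h replicate 3. Activity-regulated genes were lower at 12 h (5 of 13, 7 adjusted over the list alone, adjusted p = 0.0203 in limma's camera with an estimated correlation). Of the oxidative phosphorylation genes 23 of 40 were lower (39 adjusted over the list alone), a list that did not pass with an estimated correlation (0.169).

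The 6 h count was 335 (149 higher, 186 lower), or 106 higher and 246 lower with scaling factors from libraries without the mitochondrial genes. It was 634, 208 and 173 without control replicate 1, 2 and 3 in turn and 162 without sham replicate 1. The 12 h count was 623 (268 higher, 355 lower), and 818 (346 higher, 472 lower) without the library labelled sham 12h replicate 3, with 442 genes shared. It was 1064, 329 and 250 without control replicate 1, 2 and 3 in turn and 261 without sham replicate 1.

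At 24 h Hr38 and sr were lower than in controls on both days, Hr38 at -3.39 ± 0.42 on day 2 and -3.52 ± 0.41 on day 1, and sr at -2.17 ± 0.32 and -2.24 ± 0.30. Activity-regulated genes were lower on both days, 3 of 13 on day 2 and 5 on day 1 (7 on day 2, and 6 with 1 higher on day 1, adjusted over the list alone). The list had adjusted p in limma's camera = 0.00734 and 0.00681 with an estimated correlation. The cuticle genes Ccp84Ab (7.12 ± 1.02) and Acp1 (3.20 ± 0.57) and the antimicrobial peptide gene CecB (4.11 ± 0.94) rose on day 1, and the fatty acid synthase FASN2 (-1.46 ± 0.32) fell on day 2. On day 2 the count was 137 (81 higher, 56 lower). The split was 61 and 66 with RLE size factors, 55 and 70 with scaling factors from libraries without the mitochondrial genes, and 127 and 164 in DESeq2. It was 394, 46 and 19 without control replicate 1, 2 and 3 in turn and 25, 23 and 45 without sham replicate 1, 2 and 3. On day 1 it was 221 (149 higher, 72 lower; 237 and 198 in DESeq2), 67 and 649 without control replicate 2 and 3, and 371, 60 and 46 without sham replicate 1, 2 and 3.

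From 3 d to 15 d the sham flies were older than the controls, and transcripts of the mitochondrial genome were lower. Their share of gene counts was 12.8% ± 2.62 (SD, n = 3) in the controls of day 1. It was 6.16% ± 0.771 (n = 3) in sham at 3 d, 2.09% ± 0.338 (n = 3) at 10 d and 1.89% ± 0.347 (n = 2) at 15 d. At 10 d TBI libraries held 2.46% ± 0.513 (n = 3). At 10 d mt:Cyt-b was -5.96 ± 0.39 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.81e-10) and mt:ND4 -5.19 ± 0.38, while mt:ND6 rose at 7 d (2.07 ± 0.32). In this list, added after the data were seen, 12 of 14 genes fell at 3 d and 13 at 7 d, 10 d and 15 d, with 1 higher each time (13 lower at each time adjusted over the list alone). The p of limma's camera with an estimated correlation, not adjusted as the list was added, was 0.0118, 1.45e-04, 1.89e-04 and 0.00100 from 3 d to 15 d. It describes the list and is no independent test of it. CG11458, an uncharacterised gene, fell by 3.92 ± 0.37 at 3 d on the log2 scale, and from 27.7 ± 9.62 CPM in controls to 0.0431 ± 0.0609 CPM in sham at 15 d (n = 2).

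**Figure D5:**
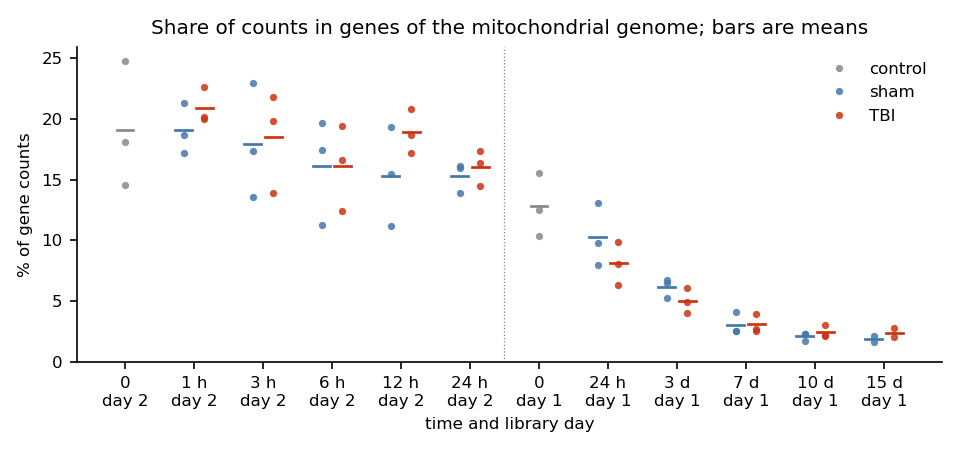
Share of gene counts from the mitochondrial genome in each library (vertical axis, percent) by time and library day (horizontal axis), with control libraries in grey, sham in blue, TBI in red and bars at the means. On day 1 the mean fell from 12.8% in controls to 1.89% in sham at 15 d, and on day 2 the means lay between 15.3% and 20.9%.

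Synaptic genes fell in sham flies at these later times. The glutamate transporter gene VGlut fell by 0.91 ± 0.12 at 3 d and by 1.42 ± 0.15 at 15 d on the log2 scale. Gad1 (-1.34 ± 0.12) and Snap25 (-1.20 ± 0.15) were lower at 10 d. Of 20 genes 19, 18, 20 and 19 were lower at 3 d, 7 d, 10 d and 15 d (20 at each time adjusted over the list alone). The adjusted p was 0.336, 0.367, 0.330 and 0.267 in limma's camera with an estimated correlation. The activity-regulated genes Hr38 (-3.75 ± 0.41 at 3 d) and sr (-2.67 ± 0.31 at 10 d) were lower. Their list passed at 3 d (7 of 13 lower, 9 lower and 1 higher adjusted over the list alone, adjusted p = 0.00882 in limma's camera with an estimated correlation). Oxidative phosphorylation genes of the nucleus fell at 7 d, 10 d and 15 d, UQCR-14 by 1.07 ± 0.09 on the log2 scale at 10 d. They numbered 29, 31 and 31 of 40 (32, 33 and 33 adjusted over the list alone, with 1 higher at 10 d). The list had adjusted p = 0.367, 0.481 and 0.267 in limma's camera with an estimated correlation. Chaperones of the endoplasmic reticulum such as Calr (0.95 ± 0.15) rose at 10 d (9 of 15, 10 adjusted over the list alone, limma adjusted p = 0.481 with an estimated correlation). Muscle genes such as Mlc2 (-1.31 ± 0.24) fell at 10 d (10 of 16 with 1 higher, over all genes and adjusted over the list alone, limma adjusted p = 0.723). Cyp4g1, an enzyme of hydrocarbon synthesis in oenocytes, rose at 15 d (11.38 ± 4.02, n = 2). It stood at 1633 and 977 CPM in sham at 15 d and at 0.487 CPM or less in the controls of day 1. The standard error draws on the spread in all groups of day 1, such as sham at 10 d (0.0659, 0.205 and 1457 CPM). CAH5, a carbonic anhydrase gene, had 0 counts in the controls and 7.91 ± 3.57 CPM in sham at 15 d (n = 2).

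The counts of sham against control were 2530 at 3 d (1092 higher, 1438 lower), 3097 at 7 d (1401 higher, 1696 lower), 4002 at 10 d (2035 higher, 1967 lower) and 3735 at 15 d (1846 higher, 1889 lower). At 3 d the count was 1225 without control replicate 2 and 1379 without sham replicate 3, and at 15 d it was 2146 without sham replicate 1. Which part of these differences follows age and which the sham procedure was not tested, as no control of the same age was sequenced.

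The library day was compared on the 9 RNAs prepared on both days, as the later times exist on day 1 only. Ribosomal protein genes were lower on day 2 (65 of 80, with 11 higher, median -1.0), as were those of oxidative phosphorylation (36 of 40, with 3 higher, median -0.88) and the proteasome (25 of 31, with 3 higher, median -0.57). Of the synaptic genes 11 of 20 were higher on day 2. The lists were not tested as sets in this comparison. Single genes with large shifts were RpL4 (-2.32), a ribosomal protein, and SdhB (-1.85), a subunit of succinate dehydrogenase. In all 6973 of 10531 genes differed, 3601 higher and 3372 lower on day 2 (edgeR with the RNA as a block), so TBI, sham and control were compared within a library day.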

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

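The tests of the library labelled sham 12h replicate 3, of the Cyp4g1 genes and of the mitochondrial transcripts below were chosen only after these patterns were seen.

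The TBI effect differed between times for 395 genes on library day 2 and for 43 on library day 1. Named genes with such a difference (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p) on day 2 were Jra (0.028), puc (0.026), TotA (9.38e-06) and repo (1.69e-04), and on day 1 Mmp1 (0.00281) and TotA (0.0479). Of 100 groupings of the libraries within times, the real one and 99 random ones, 3 with the real one gave as many genes as the 395 of day 2 (highest other 2182), and 6 of 100 as many as the 43 of day 1 (highest other 697). A regrouping that exchanges sham and TBI at some times turns the TBI effect over there and so makes differences between times itself. These counts therefore decide nothing about chance.

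The share of reads aligned at more than 1 place was above the highest control value of 6.23% in 4 libraries of day 2, a signal outside the gene counts. It was 8.13% in sham 3h replicate 3, 6.60% in sham 6h replicate 3, 16.5% in sham 12h replicate 1 and 7.71% in TBI 24h replicate 1.

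The library labelled sham 12h replicate 3 had an age score, the mean over 54 age-dependent nuclear genes, of 0.922, like flies at 7 d or later. Single genes went the other way, namely Cdc6, CG13305, lcs and CG32641. Against the other sham libraries at 12 h Cdc6 was at 3.06 on the log2 scale, where sham at 7 d was at -2.68 against 24 h. The share of mitochondrial transcripts in this library was not like that of later flies. It was 11.2%, against 1.64% to 4.10% at 7 d or later and 19.3% and 15.5% in the other sham libraries at 12 h. The 54 genes were those that differed in sham at 7 d and at 10 d from sham at 24 h of day 1. High age scores of these sham libraries were thus partly set in advance, and cannot decide on an exchange of labels with them. Their clock genes argue against one, as tim was at 116 to 166 CPM and Clk at 79.5 to 102 CPM in sham at 7 d and 10 d. In the other libraries at 12 h tim was at 1513 CPM or more and Clk at 18.1 CPM or less. The TBI libraries at 7 d and 10 d and all at 15 d were not used in the choice of the 54 genes. Their lowest age score was 0.787, against -0.184 as the highest of the other libraries of day 2. This argues against an exchange with a library of those groups. A wrong label or a sample from elsewhere fits the tim level of the library in question. It was 149 CPM, against 1513 CPM or more in the other libraries at 12 h. A second preparation of an RNA of day 1 stays open, mainly through 1 pair. Distances were taken after removing the mean shift between days. That shift was estimated from the 9 RNAs prepared on both days, so their own distances came out somewhat small. The smallest distance of this library to a library of day 1 was 0.291, above 8 of the 9 distances between libraries of the same RNA (0.142 to 0.249). Only control replicate 2 lay higher, at 0.596, and its day 1 library had 10.8% of reads not aligned and 10343 genes detected. The other controls of day 1 had 12387 and 12132 genes detected. The mitochondrial share of the library labelled sham 12h replicate 3 does not decide on an RNA of 7 d or later. It was 2.72 times the highest share of those times, where the 9 RNAs had 1.16 to 2.30 times the share on day 2. The ratio of 2.30 came from the RNA with the lowest share on day 1, TBI 24h replicate 3 (6.30%). No RNA with a share as low as at 7 d or later was prepared on both days. No biological explanation was tested.

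Cyp4g1 and the genes that rise with it were near 0 in most libraries and high in single replicates, with 43 libraries under 5 CPM and a highest value of 2773 CPM in TBI 15d replicate 2. Whole abdomens of males among the heads are argued against, as the male reproductive genes summed to at most 1.03 CPM in the 9 libraries with Cyp4g1 over 100 CPM. Abdominal wall or gut stays open, and so does female tissue in TBI 10d replicate 3. The sum of the gut genes in such a library was above that of both other replicates in 3 of 5 groups of 3, and TBI 10d replicate 3, with 817 CPM against 358 or less, also held the yolk protein transcripts (Yp1 at 632 CPM). In the other libraries with Cyp4g1 over 100 CPM, Yp1 was at most 6.21 CPM, and 2.30 CPM in TBI 15d replicate 2. This argues against female tissue with yolk transcripts as the source in those libraries. Flies shared by the sham and TBI samples of a replicate number may explain part of it: in 3 of 6 pairs both libraries were over 100 CPM, which leaves this open. All 4 libraries at 15 d were over 100 CPM, so that age stays open and untested.

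Transcripts of the mitochondrial genome were lower at later times of library day 1. That mt:lrRNA alone set the share is argued against by the protein-coding genes, with a median log2 change of -3.74 at sham 10 d. Age of the flies and date of collection cannot be told apart, as day 2 holds 0 libraries at 3 d or later.

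With 3 samples against 3 there are 10 splits of the 6 samples, too few for a share under 0.05. For TBI against sham the real and the highest other counts were 794 and 0 at 1 h, 1775 and 0 at 3 h, 1304 and 309 at 6 h, 926 and 1 at 12 h and 902 and 0 at 24 h of day 2. On day 1 they were 1587 and 0 at 24 h, 143 and 7 at 3 d, 24 and 0 at 7 d and 50 and 1 at 10 d. In each of these 1 split, the real one, gave as many genes. For sham against control they were 47 and 1 at 1 h, 137 and 133 at 24 h of day 2, 2530 and 0 at 3 d, 3097 and 1 at 7 d and 4002 and 1 at 10 d, again with 1 split as large.

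In 4 comparisons of sham with control, 2 of the 10 splits gave as many genes. At 3 h the real split gave 39 genes and that of sham replicates 1 and 3 with control replicate 1 gave 3184. At 6 h, sham replicate 1 with control replicates 2 and 3 gave 1239 against 335. At 12 h, sham replicates 1 and 2 with control replicate 1 gave 1951 against 623, and at 24 h of day 1, sham replicate 1 with control replicates 1 and 2 gave 757 against 221. Splits that call several times the real count point to a structure of the samples other than sham and control. At 24 h of day 1 the mitochondrial share went with that split, at 13.1%, 12.5% and 15.5% against 9.79%, 7.96% and 10.3%. At 3 h, 6 h and 12 h the shares of both sides overlapped. What the structure follows was not tested. For the library days 1 of 100 groupings, the real one, gave as many genes as the 6973, with 4540 as the highest other. Groupings that exchange the days of few RNAs keep much of the difference between days. No drawn grouping reached the real count, though so few draws cannot exclude chance.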

How the results depend on the processing

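The scaling without mitochondrial genes and the use of sham 12h replicate 2 alone were chosen only after the data were seen. A count is called moved below where it left the range of 1.5 times around the reported one. For the moved counts the cause was not tested, unless stated. RLE size factors moved no count, and neither did the scaling without the genes of the mitochondrial genome.

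A model of only the 2 groups compared has fewer residual degrees of freedom, and the counts it moved were lower. For TBI against sham it gave 1171 genes at 3 h, 554 at 6 h, 928 at 24 h of day 1, 62 at 3 d, 6 at 10 d and 0 at 15 d (edgeR, where 691 genes had an unadjusted p under 0.05 in the model of all groups and DESeq2 called 31). For sham against control it gave 26 at 1 h, 1 at 3 h, 49 at 6 h, 5 at 12 h, 23 at 24 h of day 2, 9 at 24 h of day 1, 480 at 3 d, 1537 at 7 d, 2608 at 10 d and 1872 at 15 d.

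DESeq2 gave more genes wherever it moved a count. For TBI against sham these were 260 at 3 d, 113 at 7 d, 117 at 10 d and 31 at 15 d. For sham against control they were 185 at 3 h, 511 at 6 h, 291 at 24 h of day 2 and 435 at 24 h of day 1. For the difference of the TBI effect between times it gave 688 on day 2 and 160 on day 1. The r of the 24 h response between library days was 0.40 with DESeq2 and 0.342 with no filter, where genes of low counts add to the genes compared. With no filter the counts were 72 and 143 for sham against control at 24 h of day 2 and day 1, 8 for TBI at 7 d and 20 at 10 d. The sum of both libraries of each RNA gave 108 for sham against control at 24 h, against 221 on day 1. With sham 12h replicate 2 alone, TBI against sham gave 338 genes and sham against control 214, and that lone sample was assumed to vary like the other groups.

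With the replicate number as a block the counts were 1372 for TBI at 24 h of day 2, 252 at 3 d and 113 at 10 d. At these times pairing was taken to hold by the rule. At 24 h of day 2 and at 10 d, however, the highest r of unlike numbers (0.130 and 0.200) was above the lowest of like numbers (0.115 and 0.192). The same RNAs at 24 h of day 1 did not meet the rule (lowest r 0.0848), so pairing at 24 h stays open. At 7 d, with 142, the rule for pairing was not met, and the 2 pairs at 15 d, with 41, were too few to decide it. The block gave 87 for sham against control at 24 h of day 2, and 821 and 119 for the difference between times on day 2 and day 1. It moved no other count.

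Of the list tests of all comparisons, 202 passed with the preset correlation, 27 with an estimated correlation and 112 with fry.

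Leaving out each library in turn gave these ranges for TBI against sham: 498 to 690 genes at 1 h, 1243 to 1641 at 3 h, 968 to 1178 at 6 h, 624 to 833 at 12 h, 562 to 857 at 24 h of day 2, 601 to 2002 at 24 h of day 1, 36 to 144 at 3 d, 0 to 40 at 7 d, 2 to 81 at 10 d and 0 to 42 at 15 d. The 0 at 7 d was reached in edgeR without sham 7d replicate 1 and without sham 7d replicate 3, and the 0 at 15 d without sham 15d replicate 2 and without TBI 15d replicate 2. With all libraries 681 and 691 genes had an unadjusted p under 0.05 at these times, and DESeq2 called 113 and 31. For sham against control the ranges were 17 to 63 at 1 h, 10 to 1527 at 3 h, 162 to 634 at 6 h, 250 to 1064 at 12 h, 19 to 394 at 24 h of day 2 and 46 to 649 at 24 h of day 1. They were 1225 to 3074 at 3 d, 2166 to 3403 at 7 d, 2981 to 4212 at 10 d and 2146 to 3944 at 15 d. The difference between times had 305 to 453 genes on day 2 and 19 to 88 on day 1, and the r of the 24 h response was 0.796 to 0.846. The libraries that moved each count are named beside it in the results above.

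Among the genes named, 511 of 519 values kept direction and side of the threshold with RLE size factors, 508 of 516 with DESeq2, 463 of 519 with no filter, 499 of 519 with the block and 387 of 510 with only the 2 groups in the model. With a library left out 2552 of 3049 did. Only Cyp4g1 in sham at 10 d changed sign, to -1.78 without sham 10d replicate 3 (10.55 without sham 10d replicate 1). Of 78 list results, all 78 kept direction and side with RLE size factors and 51 with an estimated correlation. The AP-1 and JNK list at 15 d changed direction without TBI 15d replicate 2 (limma's camera, adjusted p = 0.960, and 1.47e-04 without TBI 15d replicate 1).

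The limit that depth sets was not tested by itself. In simulated data at 24 h of day 1, 46.3% of changes of 1.5-fold and 90.9% of 4-fold were recovered, with 7 false calls of 142, and for the difference between times on day 2 86.2% of 4-fold changes were. These data too had independent genes and no outlying libraries.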

Other observations

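The test of persistence was written before its result was seen, and the yolk protein levels were looked at after. A hypothesis was that part of the 24 h response persists. Of the 804 genes higher after TBI at 24 h of library day 1, 85.4% had a positive log2 fold change at 3 d, 84.95% at 7 d, 82.0% at 10 d and 87.3% at 15 d, where of all genes 45.9%, 51.5%, 48.9% and 52.2% did. The sham and TBI libraries of 24 h are not used at these later times. The fry test of limma, which takes the correlation between genes into account, gave p = 1.78e-04, 0.00290, 0.00764 and 0.00774, with medians of 0.27, 0.19, 0.17 and 0.20. Of the 783 genes lower at 24 h, 86.7%, 81.9%, 78.5% and 82.1% had a negative value, and the p of fry was 0.109 at 3 d, 0.198 at 7 d, 0.251 at 10 d and 0.149 at 15 d. Of the 804 genes, 102 also passed as higher at 3 d, 21 at 7 d and 19 at 10 d (edgeR). A candidate explanation is thus that part of the rise lasts to 15 d, in some genes below what the test of single genes calls.

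The yolk protein genes stood out in 1 library. In TBI 10d replicate 3 Yp1 was at 632 CPM, Yp2 at 248 CPM and Yp3 at 478 CPM, where the highest values of the other 63 libraries were 11.2, 8.30 and 112 CPM.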
